A study of Mus musculus with 2 samples.

How the data were processed

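Lungs of 10-week-old C57Bl/6 mice were dissociated with collagenase after perfusion, red cells were lysed, and cell suspensions of 6 saline-treated and of 6 bleomycin-treated mice were pooled by treatment and loaded on a 10x Genomics 3' single-cell chip, per the labels' protocols. Bleomycin (100 U/kg) or saline had been given for 7 days by osmotic pump and lungs were harvested on day 21. Each group is 1 library. The deposited file of the saline pool holds raw UMI counts (unique molecular identifiers, one per captured transcript molecule) for every barcode, not normalized and with no cell calling, per the file headers and values. Cell Ranger 6.1.2, Seurat 4.1.0 and the build mm10 are named in the submitters' processing notes, with no roles given. For the bleomycin pool only the lists of barcodes and features were used; its count matrix was not analysed here, so bleomycin and saline were not compared. The matrix lists 3571202 barcodes, 21862 genes and 6 multiplexing tags. Tags held 85.0% of all UMIs and were kept apart, so that every UMI total below counts genes only. The 6 tags have separate identifiers but only 3 names, each given to 2 tags, so tags and tag groups are told apart here by identifier. No map from tags to mice was used here.

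Cells were called from barcodes with at least 500 gene UMIs, at least 250 genes and at most 15% mitochondrial UMIs that differed from the ambient profile of barcodes with at most 100 UMIs (Monte Carlo multinomial test, 1000 draws, Benjamini-Hochberg 0.01). On simulated data, 1% of 300 rows drawn from the ambient profile and 100% of 300 rows that mixed the ambient profile with that of deep barcodes were called different. Of 28785 barcodes with at least 500 gene UMIs, 13038 had fewer than 250 genes, with a median of 96.6% hemoglobin UMIs, and were left out. The filters left 14157 barcodes. Doublets were removed with Scrublet as implemented in scanpy 1.11.5, at the threshold it sets itself, or, by a rule fixed beforehand, at the top 6% of scores where that threshold marks under 0.5%. It marked 5085 barcodes (35.9%) and left 9072 cells with a median of 1568 gene UMIs (500 to 27850) and 737 genes. That threshold was not stable. It marked 27.9% with no ambient test and 0% with at most 10% mitochondrial UMIs or with at least 1000 UMIs per cell, so that the top 6% were removed in those alternatives.

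Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 gave the clusters (numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, Python 3.11.15). Genes of the collagen, collagen biosynthesis, myofibroblast, fibrocyte-associated and caveola lists were left out of clustering. Those of the pan-leukocyte (apart from Ptprc), profibrotic and dissociation stress lists stayed eligible, so their contrasts between clusters are in part circular. Clusters were named only from marker lists fixed beforehand, and a name needed at least 3 markers detected in at least 10% of cells and at least 2-fold above the other cells (pseudocount 20 CPM), with a mean log2 ratio of the list of at least 1. Counts were then summed per class and scaled to the total UMIs of the class (CPM). With 1 library per group and no map from tags to mice, tag groups were not used as replicates. No p-value, standard error or count of changed genes was made from cells. Shares carry exact Clopper-Pearson and sums exact Poisson 95% intervals, which cover counting error only. A count of 0 was given an upper limit of 3 counts. A gene was called higher in a class where its CPM differed at least 2-fold and the intervals did not overlap, which is a rule of size and not a test. The rule was run on simulated counts for 21862 genes with the totals of fibroblast-like and hematopoietic cells. It called 86% of 100 genes changed 2.5-fold, 99% of 100 genes changed 5-fold and 0.282% of the 21662 not changed. Changed genes were drawn from those with at least 100 UMIs over all cells, so their rates do not cover genes with fewer. Genes not changed had no such minimum, which can lower their rate.

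Genes named are Ptprc, Col1a1, Col1a2, Col3a1, Acta2 and Cav1 and, from each of 8 lists, up to 4 members of the highest CPM in any class and up to 2 with the largest ratio between fibroblast-like and hematopoietic cells with at least 20 UMIs in the higher class. Others, among them Fn1, Tagln, Col4a1, Col4a2, Sema7a, Plod1, P4ha1, Plod3, B2m, H2-K1, H2-D1, Actb and Ddx3y, were named after their values were seen. Each list's median log2 ratio (pseudocount 1 CPM) was set among 10000 random lists of the same size matched on total UMIs. Shares of cells with a UMI were repeated with each cell thinned to 1000 UMIs. A tag was called where its count exceeded 2 times its median in 40702 barcodes of 10 to 49 gene UMIs and at least 1000 tag UMIs. Of the 21862 gene identifiers, 21191 matched GENCODE M21 with the same version, and coordinates are from that annotation of GRCm38. Xist was not analysed here, so a check of doublets by sex genes was not run. Alternatives fixed before the data were examined were no ambient test, at least 1000 UMIs, at most 10% mitochondrial UMIs, doublets kept, Leiden resolution 2, outcome genes kept in clustering, at least 2 UMIs for a positive cell, thinning, ambient subtraction and per-cell CPM. Removal by tags, by tags and Scrublet together and of the top 6% by score were added after the data had been seen.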

Results

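Single-cell transcriptomes of lungs from saline-treated mice were measured in 1 library pooled from 6 animals. The library held 95217451 gene UMIs over all barcodes, of which hemoglobin genes took 45.0%. After cell calling and doublet removal 9072 cells with 21550144 UMIs remained. Hematopoietic cells made up 79.3% of them (95% interval 78.5 to 80.2; 7198 cells), endothelial-like cells 5.25% (476), erythroid-like cells 5.15% (467), alveolar type 2-like epithelial cells 4.60% (417), fibroblast-like cells 3.30% (299) and mesothelial-like cells 1.25% (113). Among hematopoietic cells, B-like cells were the most numerous (2676), followed by neutrophil-like (1212), T-like (1116), alveolar macrophage-like (1077), classical monocyte-like (366) and NK-like cells (323). A cluster of 129 cells named dendritic-like had none of its markers among its 10 leading genes, most of which were genes of the cell cycle. Of the B-like cells, 39 lay in a cluster led by the heat shock genes Hspa1a and Hspa1b. No cluster met the mural-like definition, and 102 cells stayed unnamed. Erythroid-like cells, at a median of 5584 UMIs of which 40.3% were hemoglobin, carried a Ptprc UMI in 74.7% of cells, and in 27.5% when thinned to 1000 UMIs. They also carried other leukocyte genes, from Laptm5 (1004 CPM against 1076 in hematopoietic cells) to Cd52 (258 against 1404). Their name rests on hemoglobin genes and Alas2, and whether they are leukocytes that carry hemoglobin was not tested. The hematopoietic share leaves them out. Of the 9072 cells, 934 (10.3%) still carried 2 or more tags, so droplets of more than 1 cell may remain among them. The class shares depended on doublet treatment: Scrublet marked 67.6% of mesothelial-like, 55.0% of epithelial-like and 50.2% of fibroblast-like barcodes against 27.9% of hematopoietic ones. With doublets kept the mesothelial-like share was 2.47% and the epithelial-like share 7.47%, and with removal by tags only the fibroblast-like share was 4.99%. Perfusion, dissociation and red cell lysis may act on these shares, which was not tested.

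The study asks which lung cells make collagen and whether these carry CD45, the leukocyte surface phosphatase encoded by Ptprc (chromosome 1, 138062861 to 138175708, GRCm38, protein-coding). Type I collagen is encoded by Col1a1 (chromosome 11, 94936224 to 94953042) and Col1a2 (chromosome 6, 4504814 to 4541544). Only the saline pool enters the comparison. Col1a1 transcripts lay almost entirely in fibroblast-like cells, which held 692 of 703 Col1a1 UMIs in called cells (98.4%, 97.2 to 99.2). Hematopoietic cells held 5 (0.711%, 0.231 to 1.65) and mesothelial-like cells 6. Fibroblast-like cells reached 850 CPM of Col1a1 (788 to 916) and hematopoietic cells 0.355 CPM (0.115 to 0.829), a ratio of 2394 (1021 to 7397). That ratio was between 682 and 1007 with doublets kept, with removal by tags only and in the 3 settings that removed the top 6% of scores. Col1a2 followed Col1a1, with 96.3% of 1451 UMIs in fibroblast-like cells. Col3a1, type III collagen (chromosome 1, 45311538 to 45349706), was shared with mesothelial-like cells, which held 25.9% of 1356 UMIs against 73.1% in fibroblast-like cells.

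All 17 measured members of the collagen and matrix list were higher in fibroblast-like than in hematopoietic cells by the size rule. Sparc, a collagen-binding matrix protein, had the highest level (2668 CPM against 3.69), followed by the proteoglycan gene Bgn (1859 against 2.34). Fibronectin transcripts were also found in leukocytes, mostly in 1 cell type. Fn1 (chromosome 1, 71585520 to 71653200) was 6.37-fold higher in fibroblast-like cells (5.86 to 6.93), yet hematopoietic cells held 71.1% of its 2958 UMIs, with a UMI in 6.86% of them. Classical monocyte-like cells held 1731 of these 2103 hematopoietic UMIs and carried 1403 CPM of Fn1 (1337 to 1470), above the 952 CPM (887 to 1022) of fibroblast-like cells by less than the 2-fold of the rule. Fn1 and this cell type were chosen after their values were seen. Against endothelial-like cells, 15 matrix members were higher in fibroblast-like cells and 2, the basement membrane collagens Col4a1 and Col4a2, were higher in endothelial-like cells.

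Of 15 collagen biosynthesis genes, 11 were higher in fibroblast-like than in hematopoietic cells and 4 differed by less than the rule. The collagen chaperone gene Serpinh1 was at 501 CPM against 0.995, Pcolce, which enhances procollagen processing, at 684 against 0.852, and Fkbp10, a collagen prolyl isomerase, at 44.2 against 0.0710. Ppib was 2.34-fold higher (2.11 to 2.58). The members that did not reach 2-fold were P4hb, at 203 against 111 CPM, Plod1 (1.90-fold), P4ha1 (1.74-fold) and Plod3 (1.17-fold). Mesothelial-like cells carried Serpinh1 at 495 CPM (449 to 545), within the interval of fibroblast-like cells (454 to 552).

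**Figure D1:**
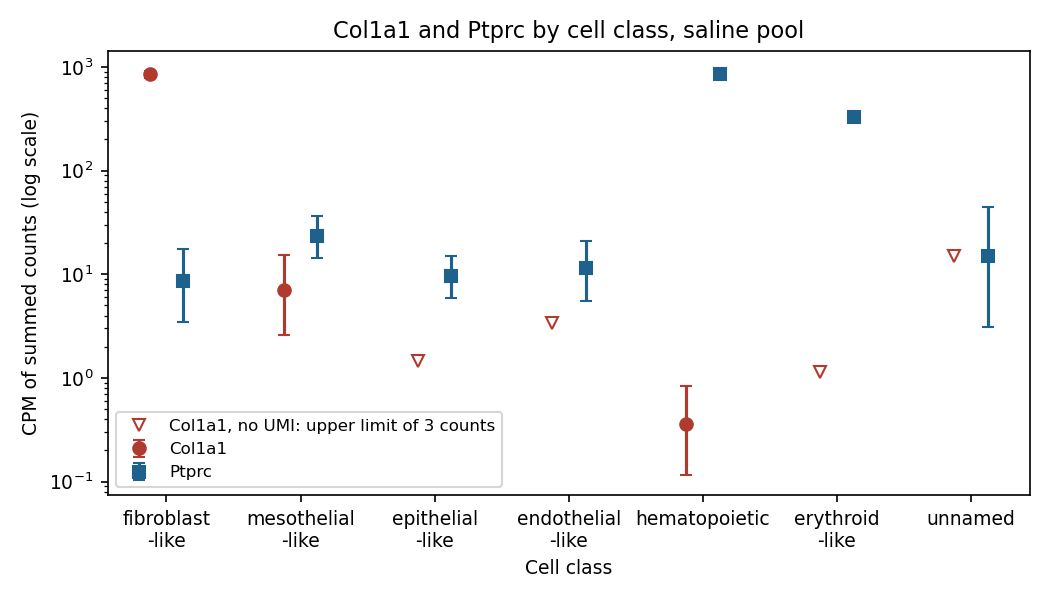
Col1a1 and Ptprc in CPM of summed counts (log axis) for each cell class of the saline pool; bars are exact Poisson 95% intervals, and open triangles mark classes with no Col1a1 UMI at the limit of 3 counts. Col1a1 reached 850 CPM in fibroblast-like cells and 0.355 CPM in hematopoietic cells, and Ptprc 8.60 CPM and 851 CPM in the same classes.

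At the Scrublet threshold, fibroblast-like cells carried Ptprc at the level of endothelial-like and epithelial-like cells. A Ptprc UMI was found in 4 of 299 fibroblast-like cells (1.34%, 0.366 to 3.39; median depth 2597 UMIs), in 8 of 476 endothelial-like cells (1.68%, 0.728 to 3.28; median 1476) and in 16 of 417 epithelial-like cells (3.84%, 2.21 to 6.16; median 4751). With each cell thinned to 1000 UMIs, which left out 30 fibroblast-like, 120 endothelial-like and 8 epithelial-like cells, the shares were 0.743%, 1.40% and 1.22%. The ambient profile gave 4.44 Ptprc-positive fibroblast-like cells. This share depended on doublet removal. It was 11.4% with barcodes of 2 or more tags removed in place of the Scrublet calls. With the top 6% of scores removed it was 10.8%, and with doublets kept 20%. The endothelial-like and epithelial-like shares under these settings are not given here, so the comparison holds for the Scrublet threshold only. Mesothelial-like cells, at a median of 5526 UMIs, had a Ptprc UMI in 14 of 113 cells (12.4%), where the ambient profile gave 2.56, and in 2.68% when thinned. Of the 113 cells 15.04% carried 2 or more tags. The other pan-leukocyte genes had a UMI in 4.42% (Cd53) to 16.8% (Srgn) of the 113, apart from Arhgdib (83.2%). Droplets that also hold a leukocyte may thus remain in this class, so the Ptprc UMIs are not shown to come from mesothelial-like cells. From the leukocyte side, 5 of 7198 hematopoietic cells had a Col1a1 UMI (0.0695%, 0.0226 to 0.162), where the ambient profile gave 5.46, and none of 476 endothelial-like cells did, which allows up to 0.630% of cells with a UMI at their median of 1476 UMIs and sets no limit on cells that express the gene. The hematopoietic share was 0.161% with at least 1000 UMIs, 0.119% with at most 10% mitochondrial UMIs, 0.130% with the top 6% of scores removed and 0.111% with doublets kept.

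Cells with UMIs of both genes numbered 6 of 9072 (0.0661%, 0.0243 to 0.144), against 6.40 if both were independent within clusters. Before doublet removal they numbered 110 of 14157 (0.777%, 0.639 to 0.936), against 102 under independence, and 86 of the 110 lay in the fibroblast-like cluster. Of these 110 barcodes Scrublet marked 104, so the count after removal rests on its threshold. With removal by tags 51 of 10391 remained, and with the top 6% of scores removed 64 of 13313. Of all 14157 barcodes 3766 (26.6%) carried 2 or more tags, so removal of the top 6% can take out only a part of these. Scrublet marked 75.2% of them at its own threshold, against 21.7% of barcodes with 0 or 1 tag. As 87.6% of fibroblast-like cells carried no tag, removal by tags cannot take out a droplet of such a cell and 1 leukocyte.

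**Figure D2:**
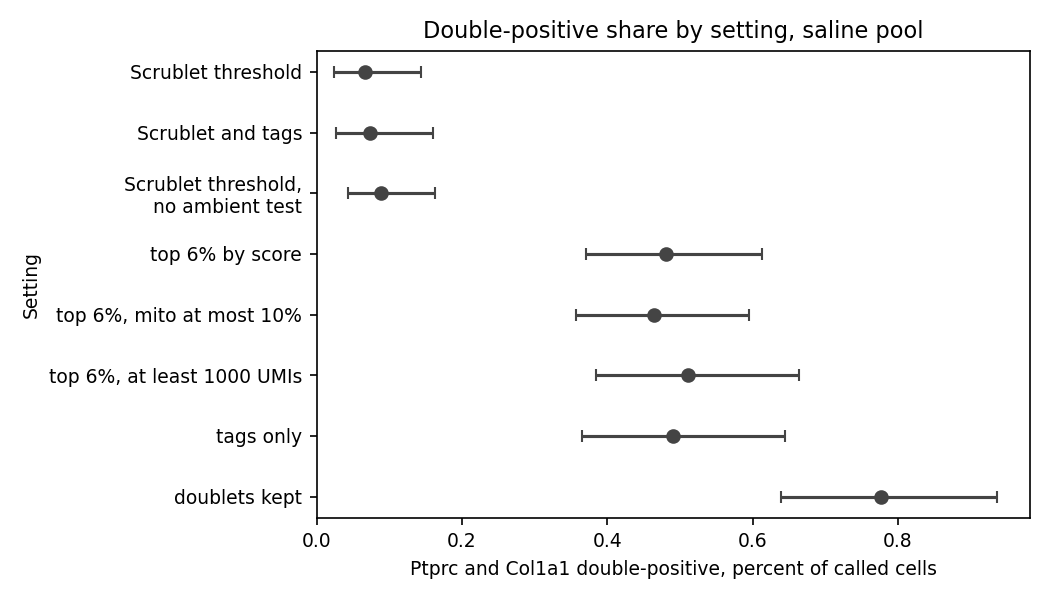
Share of called cells with at least 1 UMI of both Ptprc and Col1a1 (percent, linear axis) in the saline pool under 8 settings, of which 5 differ only in the treatment of doublets and 3 also change the ambient test, the UMI minimum or the mitochondrial limit; bars are exact Clopper-Pearson 95% intervals. The share was 0.0661% at the threshold of Scrublet, 0.491% with removal by tags only and 0.777% with doublets kept.

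Genes associated with fibrocytes, circulating cells described by leukocyte and matrix proteins together, lay mostly on the leukocyte side. Of 12 members 10 were higher in hematopoietic cells, 1 was higher in fibroblast-like cells and 1, Sema7a, met neither. Lsp1, a leukocyte cytoskeletal protein gene, was 5.28-fold higher in hematopoietic cells (4.20 to 6.73) and S100a4 7.62-fold (5.45 to 11.02), yet both were higher in fibroblast-like than in endothelial-like cells (11.4-fold, 5.27 to 29.3, and 6.11-fold, 2.54 to 17.8). The member higher in fibroblast-like cells was Cd34, a sialomucin of progenitors, vessels and stroma, at 460 CPM in fibroblast-like cells (414 to 509) against 0.639 in hematopoietic cells. Endothelial-like cells had 351 CPM of Cd34 and mesothelial-like cells 230. All 11 pan-leukocyte genes were higher in hematopoietic cells, with Tyrobp 95.5-fold (58.8 to 167), Lcp1 106-fold (48.9 to 290), Fcer1g 76.2-fold, Srgn 37.5-fold and Cd52 36.8-fold. Apart from Ptprc, these genes had stayed eligible for clustering, so this outcome is in part built in.

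Of 13 myofibroblast and contractile genes, 10 were higher in fibroblast-like than in hematopoietic cells and 3 met neither, most at low levels. Tpm2 was at 82.3 against 11.5 CPM, Myl9 at 50.4 against 19.7, Des at 24.6 against 0.781, Aspn at 28.3 against 0.0710, and Cthrc1 at 24.6 with no UMI in hematopoietic cells, at least 115-fold. Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590), gave 150 UMIs in all called cells. Fibroblast-like cells held 23 of them (15.3%, 9.98 to 22.1; 28.3 CPM) and hematopoietic cells 109 (72.7%, 64.8 to 79.6; 7.74 CPM). Neutrophil-like cells held 92, at 58.6 CPM (47.3 to 71.9), which is above fibroblast-like cells (17.9 to 42.4) by the size rule. Depth differs, at a median of 992 UMIs in neutrophil-like and 2597 in fibroblast-like cells. With cells thinned to equal depth, an Acta2 UMI was in 4.33% (2.85 to 6.29) of neutrophil-like and 1.86% (0.606 to 4.28) of fibroblast-like cells. These intervals overlap, so a higher share of positive cells among neutrophil-like cells is not shown. Thinning left out 612 neutrophil-like and 30 fibroblast-like cells. No UMI of Acta2 was found in the 2676 B-like or the 1116 T-like cells. Tagln, another contractile gene, was at 3.19 CPM in neutrophil-like cells and 35.6 CPM in fibroblast-like cells. These cell types and Tagln were chosen after their values were seen.

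**Figure D3:**
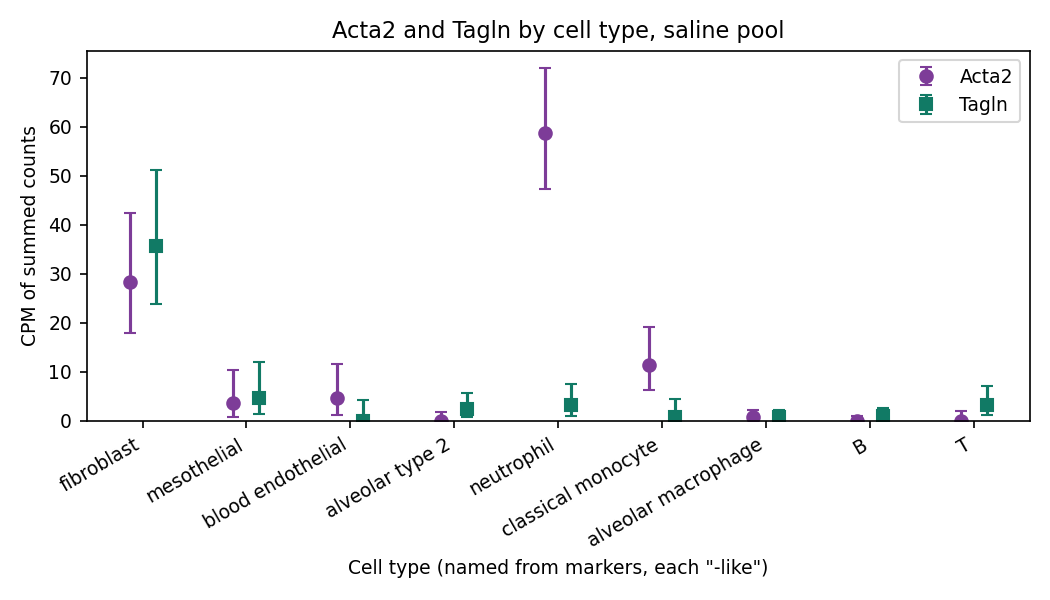
Acta2 and Tagln in CPM of summed counts (linear axis) for 9 cell types of the saline pool; bars are exact Poisson 95% intervals. Acta2 was at 58.6 CPM in neutrophil-like cells and 28.3 CPM in fibroblast-like cells, while Tagln was at 3.19 CPM and 35.6 CPM.

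Caveola genes, which build small pits of the plasma membrane, were highest outside the fibroblast-like class. Of 7 members 5 were higher in fibroblast-like than in hematopoietic cells, among them Cavin3 (429 against 1.07 CPM) and Cavin1 (192 against 4.12). Cav1 (chromosome 6, 17306335 to 17341452) was at 62.7 CPM in fibroblast-like cells, 7.53 in hematopoietic, 1035 in endothelial-like and 874 in mesothelial-like cells. Against endothelial-like cells, 4 members were lower in fibroblast-like cells, including Cav1 (16.5-fold, 12.5 to 22.4) and Cavin2 (14.3-fold, 11.5 to 17.8), and Cavin3 was higher (3.49-fold, 2.80 to 4.37).

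Of 17 profibrotic signal genes, 11 were higher in fibroblast-like and 3 in hematopoietic cells. Fibroblast-like cells were higher in the matricellular gene Ccn2 (at least 600-fold, with no UMI in hematopoietic cells), the growth factor gene Fgf2 (197-fold, 79.7 to 630.5), the chemokine gene Cxcl12 (129-fold, 92.2 to 185) and the receptor gene Tgfbr2 (2.44-fold, 2.15 to 2.76). The cytokine gene Il1b was 72.7-fold higher in hematopoietic cells (39.5 to 152). Tgfb1 (229 against 28.3 CPM) and Spp1 (127 against 2.46) were also higher there. Pdgfb had 283 UMIs in endothelial-like cells (322 CPM) and none in fibroblast-like cells. Against endothelial-like cells, 7 of the 17 were higher in fibroblast-like cells, 3 were lower and 7 met neither. Cxcl12 was among the lower ones, at 358 CPM (318 to 401) against 976 (912 to 1044). Beside these lists, 7 of 8 dissociation stress genes were also higher in fibroblast-like than in hematopoietic cells, with Egr1 at 3684 against 135 CPM, Fos at 3099 against 620 and Jun at 1707 against 299, while Junb differed 1.12-fold. None of the 8 met the rule between fibroblast-like and endothelial-like cells. The median log2 ratio of fibroblast-like over hematopoietic cells was 7.76 for the matrix, 4.35 for the biosynthesis and 3.08 for the profibrotic list (percentile 100 of matched random lists), 3.26 for the caveola and 2.25 for the stress list (99.99), 2.04 for the myofibroblast list (99.85), and -3.62 for the fibrocyte-associated and -6.03 for the pan-leukocyte list (0.01). The percentile thus did not set the matrix list apart from the stress list. For the pan-leukocyte, profibrotic and stress lists it is also in part circular, since their genes, apart from Ptprc, had stayed eligible for clustering.

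The fibroblast-like class consisted of 2 clusters. One, of 169 cells, was led by Inmt, Mfap4 and Npnt, and the other, of 130 cells, by Dcn, Clec3b and Pi16. The second was higher in Cd34 (924 against 90.4 CPM; 10.2-fold, 7.38 to 14.5), Lsp1 (3.18-fold, 1.88 to 5.55), Cxcl12 (3.44-fold, 2.64 to 4.52), Serpinh1 (2.08-fold, 1.69 to 2.55) and Pcolce (2.03-fold, 1.71 to 2.42). The first was higher in Des and Cthrc1 (both 7.15-fold, 1.71 to 63.5), Ccn2 (4.07-fold, 2.40 to 7.29) and Tgfbr2 (2.09-fold, 1.61 to 2.73). Cxcl12, Ccn2 and Tgfbr2 had stayed eligible for clustering, so their contrasts are in part built in. Col1a1 (1.94-fold, 1.66 to 2.27), Col1a2 (1.96-fold, 1.76 to 2.19) and Col3a1 (1.53-fold, 1.34 to 1.73) were above in the second cluster by less than the rule asks. Of the matrix list 2 members were higher in the first cluster, 1 in the second and 14 in neither.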

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

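All tests in this part were chosen after the result was seen, except those on ambient Col1a1 and on B-lineage genes for double-positive barcodes and the test on B2m; the tag test of ambient Ptprc, the weighting by depth, the B-lineage comparison at matched depth and the values of H2-K1 and H2-D1 were added later.

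Barcodes with UMIs of both Ptprc and Col1a1 numbered 110 before doublet removal. In this part, matched depth means at least the lower quartile of the depth of the double-positive barcodes compared. The first test asked whether the 110 carried 2 or more tags more often than other Ptprc-positive barcodes of matched depth (median 7142 UMIs against 6153). They did not: 53.6% (43.9 to 63.2) against 58.2% (56.5 to 60.0). Its prediction counted that outcome against doublets, but the test is void, because 87.6% of fibroblast-like cells carried no tag and such a cell in 1 droplet with a leukocyte would show 1 tag. A second test, added after that outcome, found Ptprc in 22.4% (17.7 to 27.8) of barcodes with at least 2 Col1a1 UMIs, in 22.7% of those with the endothelial gene Cldn5 and in 22.9% of those with the alveolar type 2 gene Lamp3, and, as these differ in depth, in 32.1% and 18.4% when weighted to the depth of the Col1a1 barcodes, so that the Col1a1 share was not above both, which is consistent with droplets that hold a collagen-expressing cell and a leukocyte. Ambient RNA is argued against as the whole source, though not by counts alone: ambient Col1a1 gave 30.7 such barcodes but ambient Ptprc 94.5, at a contamination that also counts doublets, while only 1.16% (0.0294 to 6.31) of double-positive barcodes in the fibroblast-like class lacked a tag, against 69.0% (58.0 to 78.7) of its Col1a1-positive barcodes of matched depth without Ptprc, and ambient Ptprc would reach both alike. A monocyte-lineage cell that carries both transcripts stays open, as does any other true double-positive cell, which Scrublet may remove as well: B-lineage UMIs were in 30.0% (21.6 to 39.5) of the 110 against 15.6% of classical monocyte-like barcodes, an outcome its prediction counted against it, but these were shallower, and at matched depth the share was 26.4% (21.8 to 31.4), with T-lineage UMIs in 20% and 46.6%.

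Reporter UMIs appeared in a library whose mice are labelled wild type, in features that the comparisons above do not use: 62639 UMIs of Egfp and 567 of Tdtomato in called cells. Egfp in hematopoietic cells was 1.86 times that of the ambient profile, a ratio raised by hemoglobin, which took 38.2% of the ambient UMIs. Ambient RNA alone is argued against by counts: at the contamination estimated for hematopoietic cells it gave 819 Egfp UMIs, where 55374 were observed. Reads of an endogenous gene are argued against by the tag groups, since Egfp in B-like cells was 416 CPM in the lowest of 6 tag groups and 10.5 times that in the second-lowest. In that lowest group B-like cells had 38.5 CPM of Tdtomato (18.5 to 70.8), against 3.46 (0.0876 to 19.3) in the next, with intervals that overlap narrowly, which is consistent with a reporter allele that the label does not name. A mislabelled or mixed pool was not tested apart from this, and no biological explanation was tested.

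Tags were lacking in 87.6% (83.3 to 91.1) of fibroblast-like cells, against 4.1% of hematopoietic cells. Tag counts entered the results above only where doublets were removed by tags and in the tests flagged before this one. Low depth is argued against by a median of 2597 UMIs, above the 1476 of endothelial-like cells. Low class I MHC transcripts are argued against as the whole cause by B2m, which at 746 CPM lay between 262 in epithelial-like and 1487 in endothelial-like cells, yet a part stays open, since the heavy chain H2-K1, at 538 CPM (489 to 591), lay below both (968 and 1999), though below epithelial-like cells by less than the 2-fold set for B2m, and H2-D1 was at 664 against 688 and 2405. Loss of Ptprc as the whole cause is argued against by endothelial-like and epithelial-like cells, of which 20.9% lacked a tag. The type of tag reagent is not given in the sources used here, a lower uptake by these cells stays open, and no biological explanation was tested.

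Barcodes of called cells were also in the barcode list of the bleomycin pool in 98.8% of cases, against 67.2% of saline barcodes with under 500 gene UMIs.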

How the results depend on the processing

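Removal by tags, by tags with Scrublet and of the top 6% by score were chosen after the data had been seen; the other alternatives were not. No paired analysis was possible because only 1 of the 2 groups had counts analysed here and no result comes from a test. The share of Acta2 UMIs from fibroblast-like cells stayed within its interval under all 10 alternatives run. Doublet treatment moved most other results where the Scrublet calls were replaced or dropped. Removing barcodes with 2 or more tags together with the Scrublet calls left every result within its interval. The hematopoietic share was then 79.4% and the Ptprc-positive share of fibroblast-like cells 1.02%. The double-positive share was 0.0737%, the fibroblast-like share of Col1a1 UMIs 98.6% and the Col1a1 CPM ratio 2032. With at least 1000 UMIs, at most 10% mitochondrial UMIs, doublets kept, removal by tags only and removal of the top 6%, in that order, the hematopoietic share was 69.2%, 75.6%, 70.2%, 71.8% and 75.2% (79.3% as reported), the Ptprc-positive share of fibroblast-like cells 10.2%, 11.1%, 20%, 11.4% and 10.8% (1.34%), the double-positive share 0.511%, 0.465%, 0.777%, 0.491% and 0.481% (0.0661%), the fibroblast-like share of Col1a1 UMIs 94.5%, 93.5%, 93.2%, 94.3% and 93.8% (98.4%), and the Col1a1 CPM ratio 887, 1007, 819, 682 and 937 (2394). The first pair of these settings also removed the top 6%, as Scrublet's own threshold marked none there, so they differ from the reported values through doublet treatment as well. Before doublet removal 26.6% of the 14157 barcodes carried 2 or more tags, so removal of the top 6% can take out only a part of these. The hematopoietic share of Col1a1 UMIs was 1.68% with at least 1000 UMIs, 1.70% with the top 6% removed and 0% with ambient RNA subtracted (0.711%); that subtraction gives no finite CPM ratio. The hematopoietic share was 77.0% with no ambient test, and the cause was not tested. At Leiden resolution 2 it was 78.2% of the same 9072 cells, through other cluster names. There 520 cells were erythroid-like (467 as reported) and 153 unnamed (102), while the other classes kept their counts. Asking for at least 2 UMIs, which fewer cells can meet by construction, gave 0.334% Ptprc-positive fibroblast-like cells, 0% Col1a1-positive hematopoietic cells (0.0695%) and 0.0110% double-positive cells, and thinning gave 0.0150% double-positive cells. Class assignment under no ambient test, at least 1000 UMIs, at most 10% mitochondrial UMIs and doublets kept also shifted with the floating-point arithmetic of the linear algebra library, so those values hold for the arithmetic used here, while the reported values did not shift. With 299 fibroblast-like cells, the interval of the Ptprc-positive share runs from 0.366% to 3.39%.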

Other observations

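The test of Egfp in fibroblast-like cells was set out before its result was seen; the genes, cell types and tag groups in this part were chosen after their values were seen.

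Ptprc differed widely among leukocytes. NK-like cells had 2169 CPM (2036 to 2308), neutrophil-like cells 1597 (1535 to 1661), T-like cells 985 (941 to 1031), classical monocyte-like cells 902 (850 to 956), B-like cells 601 (577 to 626) and megakaryocyte or platelet-like cells 99.2 (49.5 to 177). No Col1a1 UMI was found in the 366 classical monocyte-like cells, which allows up to 0.820% of cells with a UMI at this depth and sets no limit on cells that express the gene, and 4 of the 5 hematopoietic Col1a1 UMIs lay in B-like cells. Actb, the cytoplasmic actin gene, did not follow Acta2: it was at 15415 CPM in platelet-like cells, which had no Acta2 UMI, at 9739 CPM in alveolar macrophage-like cells, where Acta2 was at 0.745 CPM, and at 7146 CPM in neutrophil-like cells, where Acta2 was at 58.6 CPM.

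A cluster of 102 cells that met no definition was led by Myl4, Tnni3, Sln, Myl7 and Tnnt2, genes of cardiac muscle. It held Acta2 at 40.3 CPM (17.4 to 79.5) and B2m at 20.2 CPM, and 93.1% of its cells lacked a tag. The Y-linked gene Ddx3y was at 2.35 CPM (0.642 to 6.03) in hematopoietic cells of the first tag and between 92.8 and 105 CPM in those of the other 5. Tdtomato was at 162 CPM in endothelial-like, 95.1 in epithelial-like, 52.8 in fibroblast-like and 10.7 in hematopoietic cells.

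A hypothesis was that part of the fibroblast-like cells carry Egfp at the level of leukocytes. Of 299 fibroblast-like cells 9.03% (6.04 to 12.9) lay at or above the lower quartile of hematopoietic cells, against 4.56% (2.77 to 7.02) of epithelial-like and 28.4% of endothelial-like cells. The intervals of fibroblast-like and epithelial-like cells overlap, which the prediction had counted against the hypothesis. With 27 such cells the overlap is narrow and the difference too small to decide. Depth also differs, at a median of 2597 UMIs in fibroblast-like and 4751 in epithelial-like cells. The cut, set in CPM per cell, does not allow for this. With cells thinned to equal depth, an Egfp UMI was in 26.8% (21.6 to 32.5) of fibroblast-like and 27.1% (22.9 to 31.7) of epithelial-like cells. These shares show no difference, but they count any UMI and not the leukocyte level, so the hypothesis stays open.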
